A study of Danio rerio with 2 samples.

How the data were processed

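Messenger RNA was sequenced from 2 zebrafish (Danio rerio, AB strain) samples, an explant of the animal pole and an explant of the vegetal pole of fertilised eggs collected 0 to 20 min after fertilisation. Per the labels' protocols, total RNA was extracted with Trizol and mRNA libraries were made with a TruSeq RNA kit, with no selection step named. The 2 libraries were grouped by the tissue subtype label, which gives 1 library per pole and no replicates. No difference between poles therefore has a replicate check, and no p-value of this work is reported.

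The deposited expression table has 50038 rows, each an Ensembl transcript. For each library it gives the count of mapped reads, the percentage of the transcript covered, the mean read depth and the RPKM (reads scaled by transcript length and by the reads mapped in the library), per the file headers. The genome build is Zv9 per the submitters' processing notes. The aligner, the counting program, the use of strand and the treatment of reads shared between isoforms or paralogs are not given in the sources used here, so the values of transcripts with near-identical copies are uncertain. The deposited count column holds whole numbers that sum to 16533617 reads in the animal pole library and 17685736 in the vegetal pole library. The deposited coverage column is a percentage of transcript length, per the file headers. Depth, the other coverage signal that the authors deposited, multiplied by the covered length gave a median of 51.0 bases per read in both libraries.

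The deposited RPKM equalled the read count divided by transcript length and by the library's own total in the table, with a largest relative gap of 0.192% in the animal and 0.219% in the vegetal library. The RPKM was listed as 0 in every transcript with coverage under 10% or mean depth under 2, and in no other; 0 transcripts in either library departed from this. This rule was read from the values, and it set 14588 transcripts with reads to 0 RPKM in the animal library and 13741 in the vegetal library. An RPKM of 0 therefore does not mean that no read was counted.

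The second deposited table lists transcripts with a log2 fold change (vegetal over animal), a log2 counts-per-million average, a p-value and an FDR. The authors made it with edgeR, per the submitters' processing notes, with no version stated. Its settings were recovered here from the values. edgeR 4.0.16 (R 4.3.3) was run on the counts of the 24198 transcripts with at least 10 reads over both libraries, with trimmed-mean scaling and an exact test at a fixed dispersion of 0.1. This gave the same 1643 transcripts, with p-values equal to the deposited ones to within rounding. A dispersion cannot be estimated from 1 library per group, so the listed p-values rest on that assumed value.

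For each transcript the log2 ratio of vegetal to animal RPKM was computed from the deposited RPKM after adding a pseudocount of 1. The pseudocount makes the ratios of low transcripts smaller, whereas the zeros set in the RPKM column at low coverage or depth can make them larger. Transcripts with at least 1 RPKM in 1 or both libraries were kept, and a ratio of 2-fold or more was the rule of size. Ratios of reads per library total have 95% exact (Clopper-Pearson) intervals from the counts, as do shares of reads. These cover counting error only, since reads made by PCR without molecular identifiers are not independent molecules. For a transcript of 2000 nt, a floor of 3 reads corresponds to 0.0907 RPKM in the animal and 0.0848 RPKM in the vegetal library. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used.

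The steps were tested on simulated data for this comparison over all 50038 transcripts, with counts drawn from the real levels and totals. Of 200 transcripts changed 3-fold, 189 passed the 2-fold rule in the right direction, and of 200 changed 8-fold, 200 did. With no change simulated, counting error alone put 25 transcripts past the rule. The simulated RPKM had no zeros set at low coverage or depth, so this tests the calculation from reads and gives no chance count for the deposited RPKM. In the edgeR step, run on 24198 transcripts, 198 of 200 simulated 16-fold changes were listed, with 8 unchanged transcripts. All changes were towards the vegetal library, in transcripts with many reads. The counts were drawn at the same dispersion of 0.1 that the test assumed. This checks the calculation and does not test whether that dispersion holds for the real libraries.

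The rule of size, the alternatives (pseudocounts of 0.1 and 5, the filter, the scaling, a 4-fold threshold) and 18 gene lists were set before the data were examined. The table carries names for only 2 transcripts, beta actin1 and gapdh. The remaining rows have transcript identifiers, and 0 of them matched the gene name tables used here, which are keyed by gene. The gene lists, and the transcripts of vrtn and bmp2b, the genes in the title of the series, are for that reason not analysed here. The rule for naming items, which took the 15 largest ratios in each direction among transcripts with at least 5 RPKM in the higher pole, required a gene name; it was applied to identifiers, and only the first 2 in each direction are printed. The 2 named transcripts were added because the table names them. All columns of per-sample values belonged to the 2 libraries.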

Results

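Messenger RNA of the animal and vegetal poles of fertilised zebrafish eggs was profiled to ask which maternal transcripts are unequally distributed along the animal-vegetal axis. The blastodisc forms at the animal pole, and the vegetal pole holds most of the yolk. The embryonic genome is silent at this stage, so the RNA in both explants was deposited by the mother. Each pole was represented by 1 library, of 16533617 mapped reads for the animal pole and 17685736 for the vegetal pole. Reads were counted for 31041 transcripts in the animal library and 30845 in the vegetal library, and the deposited RPKM was above 0 for 16453 and 17104 of these.

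The most abundant maternal transcripts were largely, though not wholly, shared by the poles. The 5 transcripts with the highest RPKM were the same 5 in both libraries, at 12626 to 20653 RPKM in the animal and 13319 to 22107 RPKM in the vegetal library, and their log2 ratios (vegetal over animal) lay between -0.06 and 0.20. The 10 transcripts with most reads took 9.84% of the animal and 10.5% of the vegetal reads, and the first 100 took 25.8% and 25.9%. Of the 100 transcripts with the highest RPKM in each library, 71 were common to both. Among the 129 transcripts in either set, 9 were at least 2-fold higher in the vegetal library and 15 at least 2-fold higher in the animal library. Of these 15, 1 had fewer than 10 reads in the vegetal library.

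Many less abundant transcripts differed between the poles, and more of them were higher at the vegetal pole. Of 17409 transcripts with at least 1 RPKM in either library, 3405 (19.6%) were at least 2-fold higher in the vegetal library and 2224 (12.8%) at least 2-fold higher in the animal library. The vegetal share of these 5629 transcripts was 60.5% (95% exact interval 59.2 to 61.8%, which treats transcripts as independent). Of the 5629, 930 vegetal-higher and 746 animal-higher transcripts had a mean under 1 RPKM, where being kept on 1 library selects unequal values. The median log2 ratio over all transcripts kept was 0.05, with an interquartile range of -0.47 to 0.73. The correlation of log2(RPKM + 1) between the libraries was 0.868 (Pearson) across transcripts, which are not independent replicates.

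For well-counted transcripts the ratios spread more widely than counting error. Among the 4159 transcripts with at least 500 reads in both libraries, the median absolute log2 ratio was 0.39, whereas the median counting error was 0.05, and 14.5% were at least 2-fold apart. With 1 library per pole, this spread includes any variation between preparations. Of the 5629 transcripts at least 2-fold apart, 3344 had a counting interval of the read ratio wholly beyond 2-fold, 2093 of them vegetal-higher and 1251 animal-higher. The zeros set in the RPKM column at low coverage or depth widened the counts. Of the vegetal-higher transcripts 1637 were listed at 0 in the animal library, yet 1559 of these had animal reads. By RPKM recomputed from the reads, with the pseudocount of 1 added, 961 of the 1559 were less than 2-fold apart. Of the animal-higher transcripts 1185 were listed at 0 in the vegetal library, 1136 of them with vegetal reads, and 775 of these were less than 2-fold apart on that scale. The pseudocount makes the ratios of low transcripts smaller, so 961 and 775 are not numbers of read ratios under 2-fold. With RPKM recomputed from the reads, 2457 transcripts were at least 2-fold higher in the vegetal and 1467 in the animal library, of 18062 kept.

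**Figure D1:**
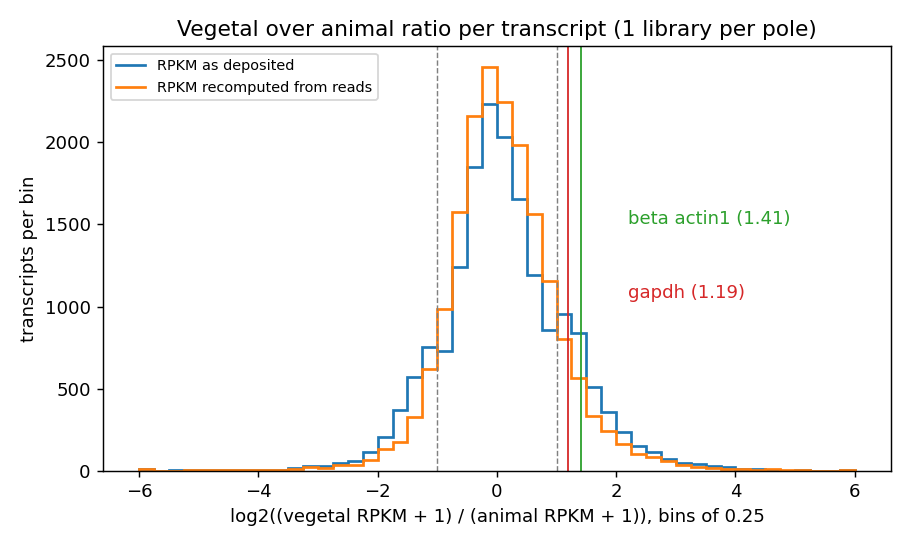
Number of transcripts per bin of the log2 ratio of vegetal to animal RPKM (pseudocount 1), from the deposited RPKM (blue) and from RPKM recomputed from the reads (orange), with 1 library per pole; values beyond 6 in either direction are in the end bins. Dashed lines mark a 2-fold difference, beyond which 3405 transcripts lay on the vegetal and 2224 on the animal side as deposited, and solid lines mark beta actin1 (1.41) and gapdh (1.19).

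The 2 transcripts that the table names were both higher at the vegetal pole. beta actin1, which encodes a cytoskeletal actin, had 29.6 RPKM (874 reads) in the animal and 80.1 RPKM (2534 reads) in the vegetal library, a read ratio of 2.71 (95% counting interval 2.51 to 2.93). gapdh, which encodes a glycolytic enzyme, had 46.1 RPKM (1014 reads) in the animal and 106 RPKM (2502 reads) in the vegetal library, a read ratio of 2.31 (2.14 to 2.48). The log2 ratio of beta actin1 was above that of 92.8% of the 500 transcripts closest to it in mean level, and that of gapdh above 92.6%. Both transcripts are often used as reference genes. Neither was in the authors' deposited table of differences, where the smallest log2 fold change of a vegetal-higher transcript was 2.001. The log2 ratios of beta actin1 (1.41) and gapdh (1.19) were below that size, so their absence from the table does not count against a difference.

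At the extremes, a few transcripts were abundant at one pole and nearly without reads at the other. ENSDART00000138373 (619 nt) had 7247 reads in the animal and 4 in the vegetal library, a read ratio of 1938 (95% counting interval 757 to 7115) in favour of the animal pole. ENSDART00000077418 (1429 nt) had 12762 reads in the animal and 8 in the vegetal library, a ratio of 1706 (866 to 3953). In the opposite direction, ENSDART00000084381 (2845 nt) had 4 reads in the animal and 4750 in the vegetal library, a ratio of 1110 (433 to 4076). ENSDART00000121756 (2140 nt) had 1 read in the animal and 4931 in the vegetal library, a ratio of 4610 with a counting interval from 827 to 182113. By RPKM with the pseudocount of 1, a scale on which a listed 0 makes the ratio depend on the level at the higher pole alone, the 15 largest ratios towards the animal pole ran from 4.72 to 9.47 in absolute log2 units, over transcripts with a median length of 920 nt. The 15 largest towards the vegetal pole ran from 4.51 to 7.04, over transcripts with a median length of 1341 nt. The other pole was listed at 0 for 14 of the former and 8 of the latter, so these ranges do not rank the poles. All 15 in each direction were in the authors' deposited table.

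The authors' deposited table, restricted to an FDR under 0.05, held 1643 transcripts, of which 1038 (63.2%) were higher at the vegetal and 605 at the animal pole. The 1038 vegetal transcripts of the authors' deposited table took 6.77% of the vegetal reads (95% exact interval 6.75 to 6.78%) and 0.876% of the animal reads (0.872 to 0.881%). The 605 animal transcripts of the authors' deposited table took 3.91% of the animal reads (3.90 to 3.92%) and 0.614% of the vegetal reads (0.610 to 0.617%). These transcripts were chosen on the same 2 libraries, so the shares are not independent evidence of the direction. The single most counted member held 6.12% of the vegetal group's reads and 7.44% of the animal group's reads. The log2 fold change of the authors' deposited table exceeded 5 in absolute size for 160 vegetal and 131 animal members. The vegetal group had a median length of 1593 nt and the animal group 1926 nt in the authors' deposited table.

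Of the 1643 transcripts in the authors' deposited table, 1415 (86.1%, 95% exact interval 84.4 to 87.8%) were also at least 2-fold apart in the same direction by RPKM. The other 228 were under 1 RPKM in both libraries, so this share counts how many of them pass the filter on level. It is no independent check, since both tables come from the same reads. Of the 5629 transcripts at least 2-fold apart by RPKM, 25.1% were in the authors' deposited table. The smallest absolute log2 fold change in that table was 2.001 for vegetal and 1.989 for animal members, whereas the 2-fold rule starts at 1. The share of 25.1% therefore compares sets with unlike limits of size and does not measure agreement. By RPKM, 741 vegetal-higher and 323 animal-higher transcripts were at least 4-fold apart. The p-values of the authors' deposited table compare these 2 libraries and equal those of a dispersion fixed at 0.1; 643 transcripts would be listed at a dispersion of 0.16 and 4959 at 0.04. The vegetal share of the list, 63.2% at 0.1, was 58.4% (2897 against 2062 transcripts) at 0.04 and 62.1% (399 against 244) at 0.16. It was 54.0% (5277 against 4504) at a dispersion of 0.01 and 53.9% (69 against 59) at 0.25, where the list is short.

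The excess of vegetal-higher transcripts was seen among short transcripts and not among the longest. Among transcripts shorter than 500 nt, 24.1% were at least 2-fold higher in the vegetal and 13.8% in the animal library (median log2 ratio 0.12, 1057 transcripts), and the vegetal share of the 2-fold transcripts was 63.6% (95% exact interval 58.7 to 68.3%). Among those of 2000 to 3000 nt the shares were 18.3% and 12.4% (median 0.02, 3236 transcripts). Among those of 6000 nt or more they were 12.6% and 17.1% (median -0.15, 475 transcripts), and the 95% exact interval of the vegetal share there, 34.3 to 51.2%, included an even split. With RPKM recomputed from the reads the shares were smaller, at 18.0% vegetal-higher and 9.02% animal-higher under 500 nt and 6.69% and 7.91% at 6000 nt or more (493 transcripts). Across the 17409 transcripts Spearman's rho of length with the log2 ratio was -0.0657. By level, 1777 transcripts had a mean under 1 RPKM, of which 52.3% were vegetal-higher and 42.0% animal-higher. Being kept on 1 library at such a mean selects unequal values. Above this, the shares were 17.1% vegetal-higher and 9.03% animal-higher at a mean of 4 to 16 RPKM. At a mean of 256 RPKM or more, 20 transcripts were at least 2-fold higher in each library, of 381. The vegetal share of the 2-fold transcripts was 65.4% (95% exact interval 62.8 to 68.0%) at a mean of 4 to 16 RPKM and 65.7% (62.3 to 68.9%) at 16 to 64 RPKM. It was lower at 64 to 256 RPKM, at 55.1% (49.1 to 61.0%), and its interval at 256 RPKM or more was wide (33.8 to 66.2%).

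**Figure D2:**
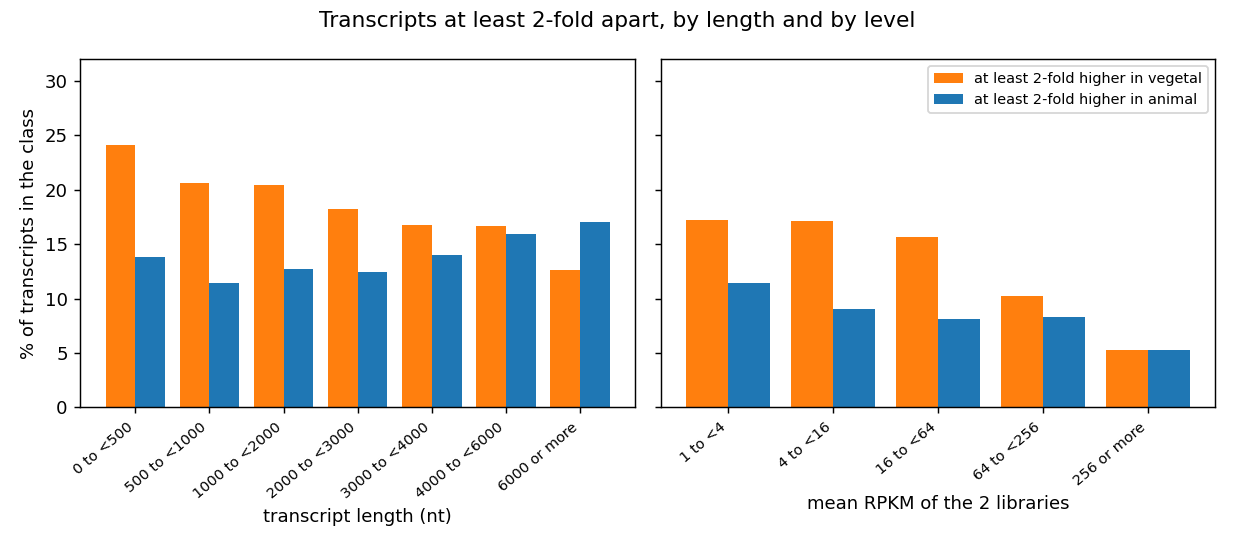
Percentage of transcripts at least 2-fold higher in the vegetal (orange) or animal (blue) library, by class of transcript length in nt (left) and of mean RPKM of the 2 libraries (right, without the 1777 transcripts with a mean under 1 RPKM), from the deposited RPKM with 1 library per pole and no error bars. The vegetal bars fall from 24.1% under 500 nt to 12.6% at 6000 nt or more, and the bars are equal at a mean of 256 RPKM or more; with RPKM recomputed from the reads, which is not drawn, the vegetal values are 18.0% and 6.69%.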

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

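The comparison of the count and RPKM columns below was chosen after the deposited values were seen. The authors' deposited table of differences holds 174 transcripts whose RPKM is 0 in both libraries, 81 of them listed as higher at the vegetal and 93 at the animal pole. The signal behind these entries is in the count columns, which the comparison of RPKM does not use. In the library with more reads they had a median of 25.5 reads and between 13 and 219. The edgeR run that gave the same list used only transcripts with at least 10 reads over both libraries, so the lowest counts were left out beforehand. They had reads but were listed at 0 under the coverage and depth rule of the RPKM column.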

How the results depend on the processing

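The recomputed RPKM, the dispersions and the alternatives for beta actin1 and gapdh were chosen after seeing the data. The excess of vegetal-higher over animal-higher transcripts kept its direction under every pseudocount, filter, scaling and threshold tried. The scalings moved the log2 ratio by only 0.052, 0.045 and -0.023, whereas a shift of 0.181 would make both directions equal. They were therefore too small to test the direction. The log2 ratios of beta actin1 (1.41) and gapdh (1.19) are larger than that shift, and scaling to these transcripts was not tried. At a pseudocount of 5 RPKM, 1144 transcripts were at least 2-fold higher in the vegetal and 565 in the animal library, and with at least 5 RPKM required in either pole, 1792 and 1004. At a 4-fold threshold the counts were 741 and 323. With RPKM recomputed from the reads they were 2457 and 1467. A pseudocount of 0.1, the 3 other scalings and the removal of the filter stayed within 1.5 times of 3405 and 2224; the last changes nothing by construction. Among transcripts in the authors' deposited table with an FDR below 0.001, 94.2% were at least 2-fold apart by RPKM, against 86.1% of all; each of the 228 that were not was under 1 RPKM in both libraries. The length of that table depends on the dispersion assumed in edgeR. It was 9781 transcripts at 0.01, 4959 at 0.04, 1643 at the value of 0.1 that gives the deposited list, 643 at 0.16 and 128 at 0.25. beta actin1 and gapdh were above 2-fold (log2 of 1) under each pseudocount and scaling. Alternatives for vrtn, bmp2b and the gene lists were not run, because the rows could not be tied to gene names. Of the 5629 transcripts 2-fold apart, 3344 had a counting interval wholly beyond 2-fold. Among those listed at 0 in one library but with reads there, 961 vegetal-higher and 775 animal-higher were less than 2-fold apart by recomputed RPKM with the pseudocount of 1. With 1 library per pole, variation between clutches and preparations was not measured and no library could be left out. No paired analysis was possible because each pole has a single library.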

Other observations

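The tests below were chosen after the data were seen, although scaling to a median log2 ratio of 0 was among the alternatives set beforehand.

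A group of 13 transcripts behaved almost as present or absent. Each had at least 2000 reads in one library and fewer than 10 in the other. The animal library held 10 of them, of 562 to 1429 nt, with 45363 reads against 19 in the vegetal library, and 4 of these had no vegetal read. The vegetal library held 3, of 1905 to 2845 nt, with 12465 reads against 8. Among the other 2081 transcripts that reach 2000 reads in a library the largest ratio was 71.7, and the smallest ratio of the 13 that could be computed was 868. The limits of 2000 and 10 reads, chosen after the values were seen, set part of this gap. In the library that held the reads, coverage was at least 50% of the transcript in each of the 13. This does not decide whether a few fragments were amplified, because a handful of other reads can cover much of a short transcript. Just 4 vegetal reads covered 27% of ENSDART00000138373. Reads moved between near-identical transcripts would leave matching gains and losses. The vegetal group held 27.5% as many reads as the animal group, which does not decide it, because reads could also go to transcripts present in both libraries. The rows are transcripts not tied to genes here, so several of the 13 may be isoforms of 1 gene, and their number is not a number of genes. RNA localisation is possible, and so is a difference in genotype between parents if the 2 explants came from different eggs. Neither was tested.

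The excess of vegetal-higher transcripts was weighed against the way the values were made. Setting the median log2 ratio to 0 left the vegetal share of 2-fold transcripts at 57.8% (95% exact interval 56.5 to 59.1%), which argues against the scaling seen by the median transcript as the whole cause. Thinning the vegetal reads to the animal total, with RPKM recomputed from the reads, gave 62.5%, and recomputation alone gave 62.6%, so neither the deeper vegetal library nor the zeros in the RPKM column is the whole cause. A shift of only 0.18 in log2 units (1.13-fold) would make both directions equal in number. A difference in total mRNA between the explants, which relative values hide, may therefore contribute and cannot be told apart from localisation without RNA of known amount.

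The fall of the log2 ratio with transcript length was also weighed. It held with RPKM recomputed from the reads (Spearman's rho -0.0677 over 18062 transcripts, and -0.0923 over the 13958 with at least 100 reads), so the zeros in the RPKM column do not produce it. Lower RNA integrity at the vegetal pole would leave long transcripts less completely covered. At matched reads (within 10%), 387 transcripts of at least 3000 nt were covered over 82.0% of their length in the vegetal and 81.2% in the animal library, a difference of 0.806 percentage points (bootstrap 95% interval 0.155 to 1.40). Matching on reads kept 16.7% of the 2320 long transcripts with at least 100 reads in both libraries. It also fixed the ratio that was to be explained, so the test does not decide, and lower RNA integrity stays open. A length-dependent distribution of maternal RNA remains a hypothesis, and the correlation is weak.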
